A study of Homo sapiens with 9 samples.

How the data were processed

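RNA of MCF-7 cells, a human breast cancer line, was hybridised to 9 Affymetrix HT HG-U133+ PM arrays, with 3 arrays each for serum-free control, insulin for 4 h and insulin for 24 h at 10 µg/mL. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on a column with DNase digestion, and labelled with biotin by a one-cycle kit. The labels of the samples give 48 h without serum for control, 44 h before 4 h of insulin, and 24 h before 24 h of insulin. The treatment protocol instead has insulin added 24 h after serum was removed, so the serum-free time before the 4 h treatment is not settled.

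The values were log2 signals of one number per probe set and array, as the authors deposited them. The scale was read from the values, and the software and normalization behind them are not given in the sources used here. Probe sets were paired with genes through the platform's annotation, and symbols were updated by gene identifier through a RefSeq table of assembly GRCh38.p14, used for names only. Of 54715 probe sets, 102 were controls, 40920 had 1 gene, 864 had several and 12835 others were not listed in the table and are unnamed here. No coordinates are given, since no genome build is named for the values.

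Groups came from the labels. Deviations of same-numbered control and 4 h arrays from their group means correlated between 0.19 and 0.50 in 3 of 3 pairs, so the numbers were taken to pair these arrays, from the values and not from the labels. The main axis of these deviations held 78.1% of the variance within groups, and replicate 1 had the highest poly-A spike-ins in both groups (6.47 and 8.42). These correlations therefore do not settle a pairing. No pair of arrays held identical values. Of several probe sets with exactly 1 gene, the one with the highest mean over all arrays stood for the gene, and genes whose mean lay below the 40th percentile of non-control probe sets (log2 2.68) were left out, which left 14221. All 9 arrays entered 1 fit with 3 group means in limma 3.58.1 (R 4.3.3), with lmFit and eBayes and Benjamini-Hochberg adjustment over the genes, and calls were made at an adjusted p under 0.05. Adjusted p-values of genes in the text come from this fit unless another is named. Gene lists (28, fixed before the data were examined) were tested with limma's camera at a preset correlation of 0.01, adjusted over 84 tests; 2 further lists were written after the data were seen, with 5 tests adjusted together. Of the 84 tests 15 passed, and 3 passed with an estimated correlation, namely ribosome biogenesis at 24 h against control and against 4 h, and cholesterol synthesis at 24 h. In none of the 15 did the median and the test differ in sign. Control probe sets for poly-A and hybridisation spike-ins, background, and the 3' and 5' ends of ACTB and GAPDH were averaged per array.

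Genes were named by a rule set before the data were examined. It took the 8 highest and 8 lowest changes against control among called genes whose arrays did not overlap, up to 3 called members per list, 8 fixed genes whatever their result, the 5 highest and 5 lowest for 24 h against 4 h, and up to 5 in each direction with opposite calls at the 2 times. Some genes that the rule allows were left out of the text for length. CYP1A2, AHRR, TIPARP and NFE2L2 in the closing section were chosen after their values were seen.

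The fit and camera were tested on simulated arrays with the real genes' control means and residual spreads. Among 14221 genes, changes of 2 on the log2 scale were recovered in 94.9% for 4 h against control and 89% for 24 h against control, and changes of 1 in 63% and 69%. False calls were 5.46% and 4.97% of the calls. The simulation drew genes independently and with 1 spread for all groups. It therefore does not cover genes that vary together or the wider spread of the 4 h arrays.

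Alternatives were quantile normalization, centring on array medians, other filters, other probe set rules, other variance priors, only the 6 arrays compared, the replicate number as a block, stricter thresholds, an estimated correlation in camera, and leaving out each array. Some were added after seeing the data, namely the poly-A spike-in level as a covariate, removal of the main axis of deviations within groups, centring on the median of the tested genes, and the replicate block over the control and 4 h arrays. For the correlation of the responses, the values for unchanged groups with each group's own spread, and with same-numbered arrays deviating together, were also added after seeing the data. Pseudocounts planned for linear signals were not needed, since the values were log2. Precision is limited by the number of arrays.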

Results

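Gene expression was measured with Affymetrix HT HG-U133+ PM arrays in MCF-7 cells, an established human breast cancer line that carries the estrogen receptor. The cells were kept without serum and were then harvested untreated (control), after 4 h of insulin or after 24 h of insulin, at 10 µg/mL. Each group had 3 arrays, 9 in all. The labels describe dishes seeded in triplicate, so the p-values measure the spread between these samples. The values were log2 signals per probe set as the authors deposited them, with array medians between 2.97 and 3.13. Of the 54715 probe sets, 14221 genes were tested, each by 1 probe set. The number of arrays limits the precision. The 24 h and control arrays had like levels of the poly-A spike-ins, bacterial transcripts added to the RNA before labelling (6.20 ± 0.07 and 6.32 ± 0.14, SD, n = 3). The 4 h arrays read 7.88 ± 0.48, which was 1.56 above control. That was the smallest possible p of an exact two-sided permutation test of 3 against 3 (p = 0.1). The 24 h arrays lay below control in the 3' minus 5' signal of ACTB (1.37 ± 0.19 against 1.63 ± 0.06) and of GAPDH (0.086 ± 0.061 against 0.21 ± 0.03), each with the smallest possible p (exact permutation p = 0.1). The 4 h arrays also differed most among themselves, with a median SD per gene of 0.25 against 0.12 in control and 0.10 at 24 h.

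**Figure D1:**
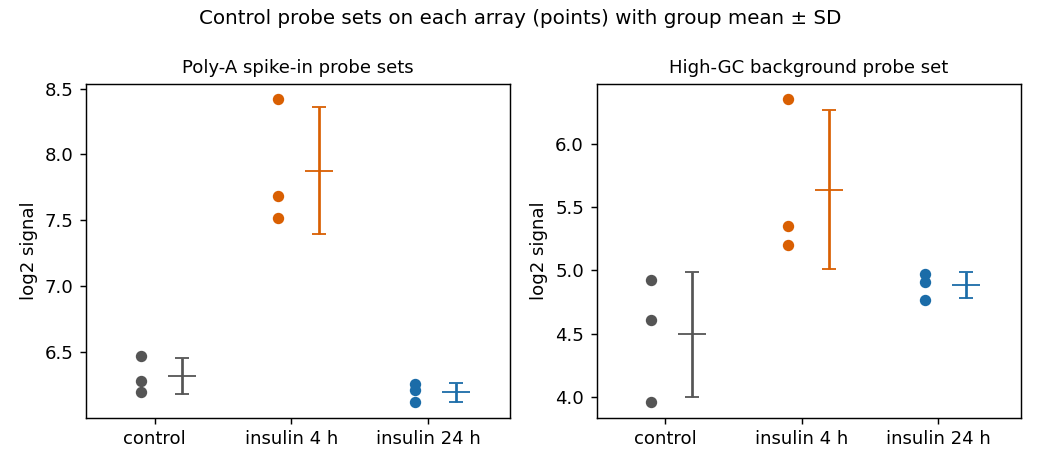
Log2 signal of the poly-A spike-in probe sets (left, mean of 24 probe sets) and of a high-GC background probe set (right) on each of the 9 arrays, with the mean ± SD of each group of 3 arrays beside the points. The 4 h arrays averaged 7.88 for the spike-ins, against 6.32 in control and 6.20 at 24 h.

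The first comparison asked what 24 h of insulin did to the transcriptome of serum-starved MCF-7 cells, in the context of the insulin and IGF-1 receptor pathway. Transcripts for dioxin-inducible cytochrome P450 enzymes showed the largest rises. CYP1A1 rose by 4.41 on the log2 scale, from 4.59 ± 0.18 in control to 8.99 ± 0.13 (SD, n = 3; limma adjusted p = 1.21e-05), and CYP1B1 rose by 3.10, from 7.79 ± 0.19 to 10.89 ± 0.08 (adjusted p = 0.00181). The tight junction gene CLDN1 rose by 2.37, FHL2 by 2.23, RGCC by 2.15 and PHLDA2 by 2.22. The deepest falls were in STON1 (-3.15), the cyclin-like gene CCNG2 (-2.26), YPEL3 (-2.23), the fibrillin gene FBN2 (-2.01), the B-cell adaptor gene BLNK (-1.92), the p53-inducible gene TP53INP1 (-1.85), PNRC1 (-1.84) and the transcriptional repressor gene HBP1 (-1.83). In all, 506 genes were higher and 443 lower, of which 101 and 71 changed at least 2-fold. In each of these 949 genes the 3 insulin arrays lay on the same side of the 3 control arrays, which chance gives for 10% of genes not selected by a test.

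Genes for making ribosomes rose together at 24 h. Of 47 tested ribosome biogenesis genes, 19 rose and 0 fell (30 and 1 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 7.68e-18). Over the 23 alternatives this adjusted p lay between 2.92e-22 and 0.00469, the highest with an estimated correlation. Examples are the small-subunit assembly factor gene PNO1 (1.06), NIP7 (1.01) and URB2 (0.96). Cholesterol synthesis genes also stood higher, with 3 of 20 called (9 adjusted over the list alone), a median of 0.51 and adjusted p = 4.58e-06 (alternatives from 5.88e-08 to adjusted p = 0.0429 with an estimated correlation). The called members were DHCR7, the enzyme of the last step of the pathway (0.65), the acetoacetyl-CoA thiolase gene ACAT2 (0.51) and the squalene epoxidase gene SQLE (0.51). Of 40 cytosolic ribosomal protein genes limma called 0, and 0 had an unadjusted p under 0.05, with a median of -0.04 (camera adjusted p = 0.329).

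Genes that respond early to growth factors, or that damp MAPK signalling, were also higher at 24 h, with 10 of 27 called and 0 lower (12 and 0 adjusted over the list alone). Their median was 0.29 and the camera adjusted p was 5e-08 (alternatives from 2.27e-09 to adjusted p = 0.122 with an estimated correlation). Among them were PHLDA2, the zinc-finger gene EGR3 (2.10) and PHLDA1 (2.08). Of 30 ATF4 target and amino acid metabolism genes, 7 rose and 1 fell (13 and 2 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 3.06e-05, alternatives from 5.82e-06 to adjusted p = 0.26 with an estimated correlation). The serine synthesis gene PSAT1 rose by 1.08, CEBPG by 1.01 and the amino acid transporter gene SLC7A5 by 0.93. Of 19 aminoacyl-tRNA synthetase genes 4 rose (5 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.00204, alternatives from 0.000313 to adjusted p = 0.26 with an estimated correlation). Among them were YARS1 at 0.59, GARS1 at 0.49 and MARS1 at 0.47.

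FOXO target genes, which the FOXO transcription factors activate when insulin signalling is low, were lower at 24 h. Of 23 tested, 7 fell and 0 rose (7 and 1 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 1.37e-05, alternatives from 7.47e-07 to adjusted p = 0.26 with an estimated correlation). CCNG2, YPEL3 and the ubiquitin ligase gene FBXO32 (-1.22) were the largest of them, and ERBB3 fell by 0.88. Of 37 mitosis and G2/M genes 5 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.00123, alternatives from 2.8e-07 to adjusted p = 0.363 with an estimated correlation). The phosphatase gene CDC25C fell by 1.2, the separase gene ESPL1 by 0.67 and the kinesin gene KIF20A by 0.47. Of 28 lysosome and autophagy genes 4 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.0198, alternatives from 0.00369 to adjusted p = 0.495 with an estimated correlation). With the spike-in covariate this list was not called either (adjusted p = 0.101). They included TP53INP1 and the autophagy kinase gene ULK1 (-0.74).

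**Figure D2:**
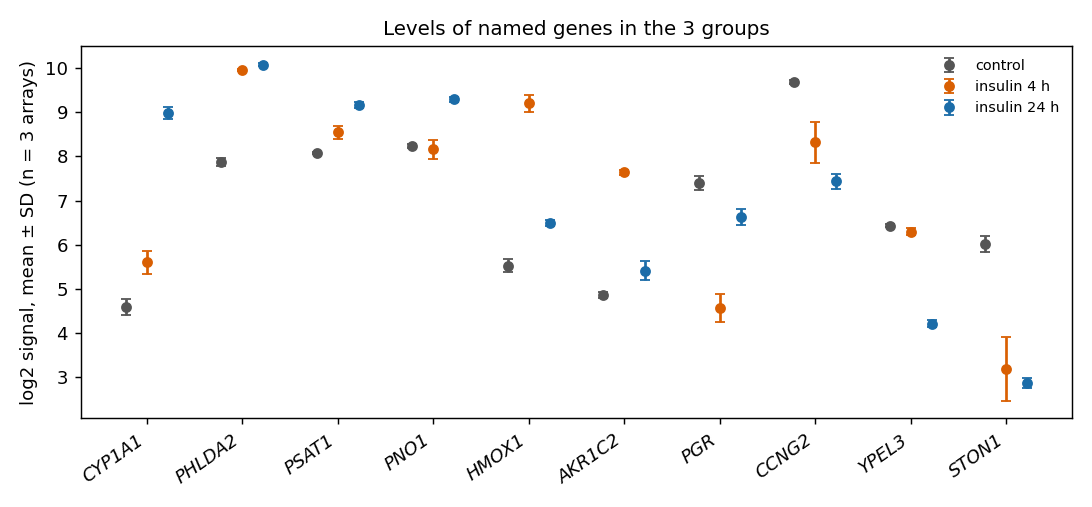
Log2 signal (vertical axis) of 10 named genes in control, 4 h insulin and 24 h insulin arrays, as the mean ± SD of 3 arrays. CYP1A1 stood at 8.99 after 24 h against 4.59 in control, HMOX1 at 9.20 after 4 h against 5.53, and YPEL3 at 4.21 after 24 h against 6.43.

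Other genes changed singly at 24 h. The insulin receptor adaptor gene GRB10 rose by 1.02 and TSC1, a brake on mTOR, fell by 0.99. The glucose transporter gene SLC2A1 rose by 0.56, the cyclin gene CCNE1 by 0.79 and the phosphatase gene CDC25A by 0.64. Among apoptosis regulators PMAIP1 rose by 1.83 and BMF fell by 1.16. The receptor tyrosine kinase gene RET rose by 1.04, the secreted protein gene AGR2 rose by 1.02 and ERBB2 fell by 0.69. Over the alternatives the limma adjusted p reached 0.433 for SLC2A1, 0.431 for ERBB2, 0.083 for CDC25A, 0.0671 for GRB10 and 0.066 for CCNE1. For TSC1, PMAIP1, BMF, RET and AGR2 it stayed under 0.05. Among list members named earlier it reached 0.258 for YARS1, 0.235 for MARS1, 0.171 for GARS1, 0.128 for SQLE and 0.125 for KIF20A. It reached 0.0963 for DHCR7, 0.0883 for ACAT2, 0.0789 for ULK1 and 0.0774 for ESPL1. Another GRB10 probe set read -0.09. Lists that did not pass included DNA replication (2 higher and 1 lower of 41, median -0.04, adjusted p = 0.831), glycolysis (4 and 0 of 19, median 0.04, adjusted p = 0.171, and adjusted p = 0.0471 without control replicate 1), fatty acid synthesis (0 and 0 of 21 in limma, 3 and 1 at an unadjusted p under 0.05, median 0.16, adjusted p = 0.0563) and estrogen receptor targets (4 and 1 of 32, median 0.19, adjusted p = 0.143). Fatty acid synthesis was called higher in 11 of 23 alternatives (adjusted p from 0.00356 to 0.263), those without 4 h replicate 1 or 2 (adjusted p = 0.00792 and 0.0381) among them. Of the markers of other cell types, limma called 0 of 10 for fibroblasts, 0 of 8 for endothelium and 0 of 5 for basal cells at 24 h. At an unadjusted p under 0.05 these were 2, 0 and 1, and 1 of 9 leukocyte markers was called higher.

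The 24 h counts depended on the arrays in the fit, which shared 1 spread with the more variable 4 h arrays. With only the 6 control and 24 h arrays, limma called 1626 genes higher and 1498 lower, and over the same 14221 genes all 949 were called again in the same direction. Without 4 h replicate 1 the counts were 1639 and 1514. Without control replicate 1, 2 or 3 they were 282, 189 and 196 higher and 199, 158 and 162 lower. Without 24 h replicate 1, 2 or 3 they were 184, 188 and 186 higher and 144, 192 and 141 lower.

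The second comparison asked what insulin did after 4 h. The labels give 44 h without serum before this treatment, but the protocol gives 24 h. These cells may therefore have spent less time without serum than control (48 h), and such a difference could not be told apart from insulin. The highest rise was that of HMOX1. The heme oxygenase gene HMOX1 rose by 3.68, from 5.53 ± 0.15 to 9.20 ± 0.20 (SD, n = 3; limma adjusted p = 1.45e-05), AKR1C2 by 2.79 and AKR1C1 by 2.59, both of the aldo-keto reductase family, and the glutathione peroxidase gene GPX3 by 2.95. The smooth muscle actin gene ACTG2 rose by 3.13, the linker histone gene H1-4 by 2.24, ISG20 by 2.20 and PFKFB4, which sets glycolytic flux, by 2.15. The progesterone receptor gene PGR fell by 2.84, COL12A1 by 2.77, ZRANB3 by 2.87 and STON1 by 2.83. NRIP1 (-2.83), CEP57 (-2.81), SKIC3 (-2.71) and PCMTD1 (-2.70) were also lower, and their fold changes had SEs of 0.68, 0.62, 0.77 and 0.57. With the spike-in level as a covariate these 4 genes were instead called higher (2.21, 1.83, 3.07 and 1.53). In all, 4725 genes were higher and 3619 lower, of which 799 and 1997 changed at least 2-fold, and the median over all tested genes was 0.15. That median was 0.17 after quantile normalization, 0.07 with each array centred on its median, and 0.27 with each array centred on the median of its tested genes.

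These counts came with the spike-in difference of 1.56 between the 4 h and control arrays, and with a high-GC background probe set that read 1.14 higher at 4 h. Without 4 h replicate 1, whose spike-ins read highest (8.42), 7902 of the 8344 calls were made again in the same direction, and 445 genes were at least 2-fold higher and 993 at least 2-fold lower. With the spike-in level as a covariate, an alternative chosen after seeing the data, 183 of the 8344 were called in the same direction and 4617 had the opposite sign. In that fit 1438 genes were at least 2-fold higher and 261 at least 2-fold lower, so the balance of the 2-fold counts turned over. Of the 41 genes named for this comparison and called, 10 were still called with the covariate, namely HMOX1, AKR1C1, AKR1C2, GPX3, PGR, COL12A1, COL1A1, CORO1A, PHLDA2 and TRIB3. Another 19 lost the call and 12 changed sign. Among the 19 only CCND1 stayed about as large (-0.40 against -0.41 without the covariate). The others shrank, some less, such as DUSP4 (1.08 against 1.32), and some more, such as STON1 (-0.54 against -2.83) and ENO2 (0.14 against 1.07). As CCND1 shows, a lost call by itself does not show that a change goes with the spike-ins, though most of these changes also shrank.

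FOXO target genes were lower at 4 h too, with 16 of 23 lower and 1 higher (16 and 1 adjusted over the list alone). Their median was -0.76 (camera adjusted p = 3.58e-05, adjusted p = 0.26 with an estimated correlation, alternatives from 6.04e-06 to 0.344). MXI1, a MYC antagonist, fell by 1.82, the stress-response gene SESN3 by 1.54 and CCNG2 by 1.37. With the spike-in covariate the median of the list was -0.29 (camera adjusted p = 0.344), but the called members turned over to 6 higher and 1 lower. In that fit MXI1 (-0.49) and SESN3 (-0.90) were not called, and CCNG2 was 0.026. Of 19 glycolysis genes 15 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 0.000398, alternatives from 1.91e-05 to adjusted p = 0.367 with an estimated correlation). The aldolase gene ALDOC rose by 1.69, GPI by 1.12 and the enolase gene ENO2 by 1.07. With the covariate the median was 0.42 (adjusted p = 0.0416), and none of these 3 genes was called. Of 30 ATF4 target and amino acid genes 23 rose and 4 fell (23 and 4 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 0.00225, alternatives from 0.000198 to adjusted p = 0.363 with an estimated correlation). Among them TRIB3 rose by 1.39, the serine synthesis gene PHGDH by 1.35 and SLC1A4 by 1.31. With the covariate the median was 0.43 (adjusted p = 0.0268), PHGDH was not called (0.47) and SLC1A4 was -0.39. Of 28 lysosome and autophagy genes 16 rose and 3 fell (16 and 3 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 0.0374, adjusted p = 0.561 with an estimated correlation, alternatives from 0.00624 to 0.747). The list passed in 16 of 24 alternatives. Besides the estimated correlation and the covariate, it did not pass without 4 h replicate 2 (median 0.63, adjusted p = 0.0532), with the replicate number as a block over the control and 4 h arrays (adjusted p = 0.0825), with only the 6 arrays compared, with the mean of the probe sets, centred on the tested genes, or with the axis within groups removed. The lysosomal regulator gene TFEB rose by 1.67 and ATG2A by 1.12, but neither was called with the covariate, where the median of the list was 0.14 (adjusted p = 0.747).

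Some lists called at 24 h were not called at 4 h. Over all genes 33.2% were called higher and 25.4% lower at 4 h, and counts of members near such shares show nothing particular to a list. Mitosis and G2/M had 13 genes higher and 15 lower of 37 (median -0.20, adjusted p = 0.682). It was called higher with the spike-in covariate (median 0.60, adjusted p = 1.14e-06) and with the main axis within groups removed (median 0.35, adjusted p = 0.00129), and its other alternatives reached 0.88. In all, 10 of the 28 lists were called at 4 h with the covariate but not in the fit of 9 arrays without it. Higher were 7, namely mitosis, cholesterol synthesis, E2F and G1/S regulators, proteasome, hypoxia-inducible genes, unfolded protein response and interferon-stimulated genes, and lower were 3, namely cytosolic ribosomal proteins, fibroblast markers and leukocyte markers. Ribosome biogenesis had 16 genes higher and 18 lower of 47 (adjusted p = 0.519), with WDR43 (-1.94), POLR1F (-1.86) and NOP58 (-1.68) among the lower. With the covariate these 3 genes changed sign (1.34, 0.44 and 1.16), and NOP58 was called higher. The early-response list had 11 higher and 1 lower of 27 (adjusted p = 0.368), with PHLDA2 up by 2.09 and the phosphatase gene DUSP4 up by 1.32. Another DUSP4 probe set went the other way (-0.47). Markers of other cell types gave 3 of 10 fibroblast genes higher, ACTA2 (1.19) and COL1A1 (1.01) among them, and 1 of 9 leukocyte genes higher, CORO1A (1.78). Neither list passed (adjusted p = 0.562 and 0.335). With the covariate both were called lower (medians -0.52 and -0.60), and ACTA2 was -0.54. At least 1 further probe set of the same gene had the opposite sign for 8 of 59 named calls with other probe sets above the filter.

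**Figure D3:**
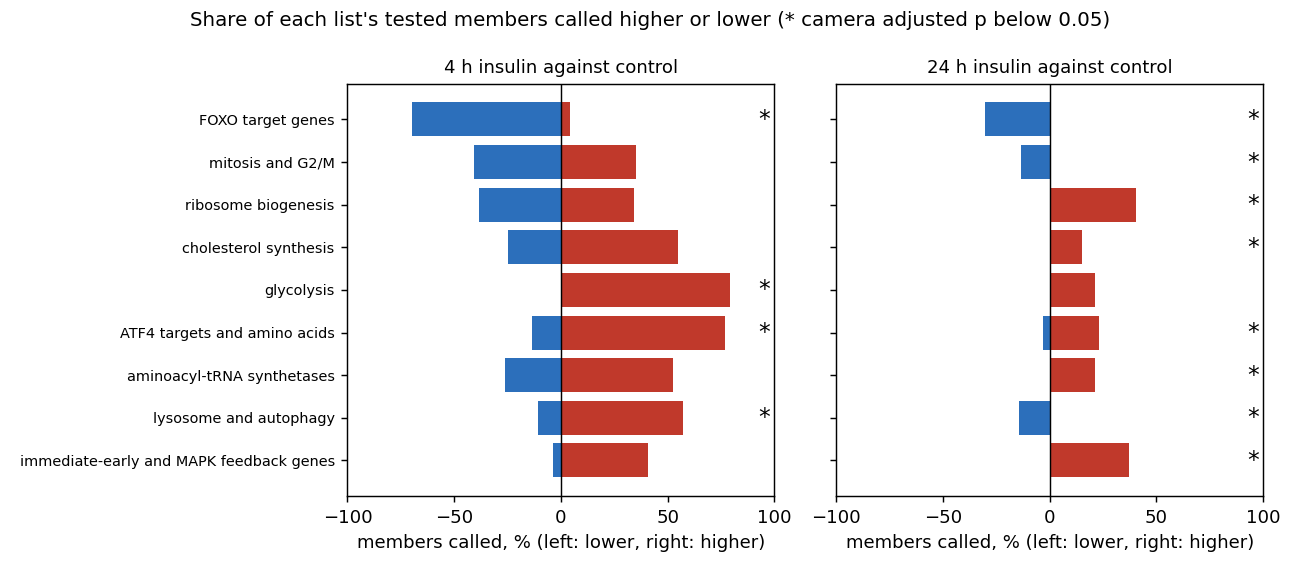
Percent of each list's tested members called higher (right) or lower (left) at 4 h and at 24 h of insulin against control (horizontal axis), for the lists called by camera at either time, with a star where the list passed. Ribosome biogenesis had 19 of 47 genes higher and 0 lower at 24 h, and FOXO target genes had 16 of 23 lower at 4 h.

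Genes of the insulin and hormone pathways were reported whatever their result. The insulin receptor gene INSR was -0.78 against control at 4 h (adjusted p = 0.0019) and -0.28 at 24 h (adjusted p = 0.269). IGF1R was -0.55 at 4 h (adjusted p = 0.00748) and -0.32 at 24 h (adjusted p = 0.195), and at 4 h another of its probe sets read 0.56 and the spike-in covariate gave 0.22. With the covariate INSR (-0.53), IRS2 (-0.71), MYC (-0.68) and CCND1 (-0.40) also lost their 4 h calls but kept their sign, and ESR1 was 0.64. IRS2 fell by 0.92 at 4 h and was -0.21 at 24 h (adjusted p = 0.346), and IRS1 was 0.16 and 0.02 (adjusted p = 0.331 and 0.963). MYC fell by 1.0 at 4 h and was -0.27 at 24 h (adjusted p = 0.177). CCND1 was -0.41 at 4 h (adjusted p = 0.013, and 0.0559 with the replicate block) and 0.35 at 24 h (adjusted p = 0.104). PGR fell at 4 h and by 0.78 at 24 h (adjusted p = 0.0335). The estrogen receptor gene ESR1 was -0.68 at 4 h (adjusted p = 0.0152), but 5 of its 6 other probe sets above the filter had the opposite sign and the mean of its probe sets was 0.089. At 24 h ESR1 was -0.07 (adjusted p = 0.911). Over the alternatives the 24 h adjusted p (limma) went down to 0.00146 for IGF1R, 0.0104 for MYC and 0.0147 for CCND1. These 3 were called at 24 h with only the 6 arrays compared and without 4 h replicate 1, among others.

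The third comparison set 24 h against 4 h of insulin. Between these times 3754 genes were higher and 4831 lower at 24 h, of which 2097 and 1067 changed at least 2-fold (1176 and 663 without 4 h replicate 1). With the spike-in covariate the 2-fold counts were instead 367 higher and 1713 lower. CYP1B1 (4.17), CYP1A1 (3.39), the WNT antagonist gene DKK1 (3.36), CLDN1 (3.20) and PMAIP1 (3.12) were higher, and HMOX1 (-2.71), GPX3 (-2.65), GPX2 (-2.40), LIN37 (-2.31) and AKR1C2 (-2.23) were lower. Genes called with opposite signs against control included LIN37, SYT17, PPP1R13L, PPARD and MXD3, which rose at 4 h and fell at 24 h, and DKK1, ARAP2, BAG2, PMAIP1 and RND3, which fell at 4 h and rose at 24 h. Over the alternatives the limma adjusted p between the times reached 0.685 for BAG2, 0.337 for ARAP2, 0.322 for RND3, 0.193 for SYT17 and 0.0529 for PPP1R13L. For LIN37, PPARD, MXD3, DKK1 and PMAIP1 it stayed under 0.05. Another ARAP2 probe set read -0.43 between the times. Ribosome biogenesis was higher at 24 h than at 4 h (29 higher and 7 lower of 47, 29 and 7 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 1.37e-05, alternatives from 5.14e-12 to adjusted p = 0.0429 with an estimated correlation). Glycolysis was lower (1 higher and 14 lower of 19, 1 and 15 adjusted over the list alone), with a median of -0.49 (camera adjusted p = 0.00658, alternatives from 0.000825 to adjusted p = 0.495 with an estimated correlation). With the spike-in covariate glycolysis was not called (median -0.32, adjusted p = 0.35). Lysosome and autophagy genes were lower too (0 higher and 20 lower of 28, 1 and 20 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 0.00123, adjusted p = 0.363 with an estimated correlation, alternatives from 8.31e-05 to adjusted p = 0.615 with the spike-in covariate). The same spike-in difference lies between these groups, with the 24 h arrays at -1.68.

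Across the 14221 genes, which are not independent replicates, the 4 h and 24 h log2 fold changes had r = 0.071 and a covariance of 0.0188. Unchanged groups against the same 3 controls gave r = 0.50 and a covariance of 0.0275 on average in 1000 simulations with 1 spread per gene, and r = 0.26 and 0.00917 with each group's own spread. The value computed for same-numbered arrays that deviate together was r = -0.14, with a covariance of -0.0045. That last value also pairs the 24 h arrays by number, which their deviations did not show. The observed r lay below both simulated values, and the observed covariance lay between theirs. No value was computed with only the control and 4 h arrays deviating together, so no difference from unchanged groups was read from these. Without control replicate 1 r was 0.21 and without 24 h replicate 2 it was -0.023. Genes higher at both times numbered 259, against 168 for independent lists, and genes lower at both times 131, against 113. There were 149 genes higher at 4 h and lower at 24 h, against 147 for independent lists, and 65 lower at 4 h and higher at 24 h, against 129. Both responses were taken against the same 3 controls, which could not be split into parts of at least 2 arrays. The F test over the 3 groups called 8967 genes.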

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

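Responses at 24 h and 4 h were compared by the limma test of the difference itself, in which 79 of the 93 genes named in the text differed, 38 higher and 41 lower at 24 h (log2 differences, 3 arrays per time). Among all 14221 genes 8585 differed (60.4%). Many named genes were chosen for a large change, so a high share among them was built in. With the spike-in covariate 478 genes were higher and 1932 lower at 24 h than at 4 h. The differences that follow come from the fit without the covariate, for the 79 named genes that differed. The higher ones began with CYP1B1 (4.17), CYP1A1 (3.39), DKK1 (3.36), CLDN1 (3.20), PMAIP1 (3.12), ARAP2 (3.03), BAG2 (2.80), SKIC3 (2.76), COL12A1 (2.70), RND3 (2.64), WDR43 (2.56), NRIP1 (2.56) and EGR3 (2.40). Intermediate differences were those of POLR1F (2.37), CEP57 (2.33), FHL2 (2.21), NOP58 (2.15), PGR (2.06), ZRANB3 (1.86), MXI1 (1.77), RET (1.72), RGCC (1.63), PHLDA1 (1.55), NIP7 (1.25), PNO1 (1.14) and SQLE (0.94). Smaller positive differences were those of CCND1 (0.75), MYC (0.74), IRS2 (0.71), CEBPG (0.64), PSAT1 (0.61), ESR1 (0.61), DUSP4 (0.58), GRB10 (0.57), INSR (0.50), CCNE1 (0.41), URB2 (0.41) and GARS1 (0.24). The lower ones began with HMOX1 (-2.71), GPX3 (-2.65), GPX2 (-2.40), LIN37 (-2.31), AKR1C2 (-2.23), H1-4 (-2.21), PPARD (-2.15), MXD3 (-2.14), YPEL3 (-2.09), PNRC1 (-2.09), AKR1C1 (-2.07), SYT17 (-1.89), PFKFB4 (-1.89) and PPP1R13L (-1.82). Less negative differences were those of ATG2A (-1.81), TFEB (-1.62), ULK1 (-1.58), ESPL1 (-1.53), ALDOC (-1.49), CDC25C (-1.44), PHGDH (-1.34), ERBB2 (-1.32), ISG20 (-1.29), GPI (-1.18), ACTG2 (-1.17), CORO1A (-1.15), COL1A1 (-1.13) and BMF (-1.08). The smallest negative differences were those of TRIB3 (-1.03), ENO2 (-0.92), CCNG2 (-0.89), KIF20A (-0.78), TP53INP1 (-0.75), MARS1 (-0.67), TSC1 (-0.67), BLNK (-0.58), HBP1 (-0.56), ERBB3 (-0.54), FBXO32 (-0.47), YARS1 (-0.46) and ACAT2 (-0.28). Gene lists that differed were ribosome biogenesis (median 0.55), glycolysis (-0.49) and lysosome and autophagy (-0.58). The last 2 were not called with an estimated correlation (adjusted p = 0.495 and 0.363) or with the spike-in covariate (adjusted p = 0.35 and 0.615).

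Some control probe sets, which were left out of the genes tested, had higher means on the 4 h arrays than on the control arrays. The difference was 1.56 for the poly-A spike-ins, 0.47 for the hybridisation spike-ins and 1.14 for a high-GC background probe set (log2, 3 arrays each). Exact two-sided permutation tests gave p = 0.1, 0.2 and 0.1, where 0.1 is the smallest possible. A low-GC background probe set differed by 0.026 (exact permutation p = 0.6).

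Tests chosen only after the result was seen were the use of the planned fit without 4 h replicate 1 as a test of that array, and those of spike-in levels at 24 h, of the 4 genes with the spike-in covariate and of the 14 other NRF2 target genes, as well as the spike-in covariate itself and the 2 further gene lists, written after the top genes were known. The first pattern is that the 4 h arrays stood apart from the rest. A part of a shorter serum-free time, which the treatment protocol gives for the 4 h cells, was not tested. A labelling or hybridisation difference is a candidate explanation, since control replicate 1, whose spike-ins read 0.23 above those of the other controls, differed from them across genes as the 4 h arrays differed from the 24 h arrays (r = 0.55 across genes, no array in common). Control replicate 1 and 4 h replicate 1 deviated alike from their group means (r = 0.50), so these differences may not be independent. Replicate 1 of the 4 h group alone does not account for it, because 8319 genes were called without that array. An insulin response in the FOXO target genes beyond this difference stays open. With the spike-in covariate their median was -0.29 (adjusted p = 0.344; over all alternatives from 6.04e-06 to 0.344), with 6 members called higher and 1 lower. The spike-ins and the 4 h treatment cannot be told apart for these genes because every 4 h array had higher spike-ins.

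The second pattern is the rise of HMOX1, AKR1C1, AKR1C2 and GPX2 at 4 h. Whether a labelling difference that moves with the spike-ins is the whole cause for these genes stays open. All 4 were still called higher with the spike-in covariate, HMOX1 by 3.01, AKR1C2 by 2.61, AKR1C1 by 2.52 and GPX2 by 1.38 (limma, highest adjusted p = 0.0288). Whether the AKR1C1 and AKR1C2 probe sets also read each other's transcripts was not tested. Without the covariate, 2 other AKR1C1 probe sets above the filter rose by 2.79 and 0.49 at 4 h. Every 4 h array had higher spike-ins, so the covariate rests on differences within groups and cannot tell labelling from treatment. For NRF2 target genes as a group a labelling difference stays open as well, because their median of 0.56 with the covariate (0.57 without) had an SE of 0.35. That SE was taken over the 18 member genes as if independent and does not measure the spread between arrays. Camera still called the list with the covariate, with 8 higher and 0 lower (adjusted p = 8.45e-05; over the 3 fits at 4 h from 8.45e-05 to 0.00147). A rise of NRF2 target genes as a group stays open too, since the 18, with a median of 0.63 without 4 h replicate 1, include HMOX1, AKR1C1, AKR1C2 and GPX2. The 14 others had a median of 0.54 in that fit, with 11 higher and 2 lower, and passed camera there and with the covariate (adjusted p = 0.0263 and 0.0126 over 3 tests) but not with an estimated correlation (adjusted p = 0.0792 each) or in the fit of 9 arrays (adjusted p = 0.0644).

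The third pattern is the rise of CYP1A1, CYP1B1 and CYP1A2 (1.98) at 24 h. The values argue against a labelling difference that moves with the spike-ins, since mean spike-in levels at 24 h and in control differed by -0.12 (SE 0.09). A candidate explanation, as a hypothesis, is activity of the aryl hydrocarbon receptor (AHR), because 4 of its 9 other tested target genes, AHRR, SLC7A5, TIPARP and NFE2L2, were higher with the 6 arrays (AHRR and SLC7A5 with all 9 arrays; camera adjusted p = 0.0233 over 5 tests, adjusted p = 0.0779 with an estimated correlation). SLC7A5 also belongs to the ATF4 list, the median of the 9 was 0.096, and whether the CYP1A2 probe set also reads CYP1A1 was not tested. The NRF2 target list was higher at 24 h too with the 6 arrays, with 7 higher and 1 lower of 18 and a median of 0.19. Its camera adjusted p was 0.008 over the same 5 tests, and an estimated correlation was not run for it. HMOX1 was 0.96 at 24 h (limma adjusted p = 0.00392). A part of the lower 3' to 5' signal at 24 h, of insulin, of the medium or of the length of serum-free culture was not tested.

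Other splits of the arrays were too few, 10 for 3 arrays against 3, for a share under 0.05. Against control, only the real split (1 of 10) reached 8344 genes at 4 h and 949 at 24 h, and the highest of the others was 0 each time. For 4 h, where the numbers were taken to pair the arrays, this holds for the 3 other splits that part 3 pairs and for the 6 that part 1. Between 24 h and 4 h, 1 of 10 splits reached 8585, and the highest other was 0. For the 3 groups together chance is unlikely but not excluded, as 1 of 100 splits drawn from 280, the real one, reached 8967 genes. Such splits take the arrays as exchangeable, which the unsettled pairing leaves open. The highest other split called 6753.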

How the results depend on the processing

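Tests chosen only after seeing the data were the spike-in covariate, removal of the main axis within groups, centring on the median of the tested genes, and the replicate block for the 6 control and 4 h arrays. Of 2479 pairs of a named gene and an alternative, 2340 kept direction and side of the threshold, 111 lost the call, 13 gained it and 15 changed sign. Lists called numbered 15 of 84 tests, and between 3 (estimated correlation) and 31 (axis removed) under alternatives of as many tests.

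Calls at 24 h against control (506 higher, 443 lower) were 1626 and 1498 with only the 6 arrays compared, 1597 and 1891 with the spike-in covariate, 2302 and 2344 with the axis removed, 223 and 156 centred on the median of the tested genes, 168 and 132 at adjusted p under 0.01, and 144 and 106 against a fold of 1.2 (treat). With every probe set by itself 873 were higher. Leaving out 1 array gave 184 to 1639 higher and 141 to 1514 lower. The highest of these were without 4 h replicate 1 and the lowest without a 24 h array, and fewer arrays alone do not explain a higher count. The 4 h arrays enter the 24 h calls through the shared spread, and they varied most (median SD 0.25 against 0.12 in control and 0.10 at 24 h). Stricter criteria lowered the counts at adjusted p under 0.01 and with treat. For the other alternatives the cause was not tested. The share of calls that were higher was 53.3%, 47.7% after quantile normalization and 58.8% centred on tested genes.

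By their deviations the numbers were taken to pair the control and 4 h arrays, but not the 24 h arrays with either. The labels do not give such a pairing, and it stays unsettled. Deviations of same-numbered arrays correlated between -0.42 and 0.50 over all 9 pairs, over 0.1 in 4, and 4 of 9 arrays correlated best with their own number. With the replicate block over the 9 arrays, 24 h calls were 311 and 240. With the block over the control and 4 h arrays, 4 h calls were 4015 and 2916, CCND1 and the lysosome and autophagy list lost their call, and no other named gene or list changed its call.

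At 4 h the covariate gave 1657 higher and 371 lower, mostly other genes or directions, since 183 of the 8344 calls were shared in direction. Treat gave 2818 higher, adjusted p under 0.01 gave 1767 lower, and single probe sets gave 8463 and 8012. For 24 h against 4 h the covariate gave 478 higher and 1932 lower, adjusted p under 0.01 2061 higher, treat 2997 lower, and single probe sets 8657 and 8281. The F test gave 5567 (adjusted p under 0.01), 17698 (probe sets) and 4818 (covariate). More tests explain the probe set counts, and stricter criteria those at adjusted p under 0.01 and with treat. For the rest the cause was not tested. The correlation of responses was -0.088 with the covariate, 0.22 with the axis removed, and from -0.023 (without 24 h replicate 2) to 0.21 (without control replicate 1) leaving out 1 array.

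Signs changed at 4 h with the covariate for ACTA2 (-0.54), CCNG2 (0.026), CEP57 (1.83), ESR1 (0.64), IGF1R (0.22), NOP58 (1.16), NRIP1 (2.21), PCMTD1 (1.53), POLR1F (0.44), SKIC3 (3.07), SLC1A4 (-0.39) and WDR43 (1.34), with the axis removed for SKIC3 (0.30) and ESR1 (0.0069), and with the mean of probe sets for ESR1 (0.089). Of 84 list medians 22 changed sign with the covariate. In 5 of them the list was called in either fit, all with the covariate, namely fibroblast markers (-0.52 at 4 h, 0.93 for 24 h against 4 h), leukocyte markers (-0.60 and 0.61) and mitosis (0.60 at 4 h). With the axis removed, fibroblast markers were 0.36 for 24 h against 4 h and mitosis 0.35 at 4 h. The cause was not tested. Pseudocount alternatives were not run, since the values are log2. Signal over background limits dim genes, and 40% of probe sets lay below the filter.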

Other observations

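The correlations with gene length and with the main axis within groups were chosen only after the data were seen. Several fixed lists held members that moved at 24 h although the list did not pass. Over all genes 3.56% were called higher and 3.12% lower at 24 h, and some of these counts lie near such shares. Hypoxia-inducible genes had 4 higher and 2 lower of 17 (median 0.20, adjusted p = 0.187), p53 targets 3 and 3 of 21 (0.01, adjusted p = 0.928), and unfolded protein response genes 2 and 1 of 22 (0.10, adjusted p = 0.187). E2F and G1/S regulators had 2 higher and 0 lower of 21 (0.06, adjusted p = 0.143), luminal markers 1 and 2 of 18 (-0.11, adjusted p = 0.143), insulin and IGF receptor signalling genes 2 and 1 of 29 (-0.08, adjusted p = 0.187), interferon-stimulated genes 1 and 1 of 26 (-0.11, adjusted p = 0.494, and 0.0408 without control replicate 1) and apoptosis regulators 1 and 2 of 21 (-0.09, adjusted p = 0.562). For the proteasome limma called 0 of 28 (1 at an unadjusted p under 0.05), for oxidative phosphorylation 0 of 36 (0 unadjusted) and for replication-dependent histones 0 of 17 (0 unadjusted).

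With the 6 control and 24 h arrays alone, fatty acid synthesis (adjusted p = 0.00375) and estrogen receptor targets (adjusted p = 0.0443) passed as well. With an estimated correlation, run on all 9 arrays only, neither passed (adjusted p = 0.263 and 0.363). Across genes, which are not independent replicates, the 4 h log2 fold change went with gene length (Spearman -0.32), as did the difference of control replicate 1 from the other controls (-0.21), while the 24 h change did so less (-0.03). The main axis of deviations within groups held 78.1% of their variance and correlated at 0.86 with the 4 h change and at -0.05 with the 24 h change.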
